A study of Mus musculus with 13 samples.

How the data were processed

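Brain RNA from 13 male mice was measured in 4 groups, sham_CON, sham_DE, tMCAO_CON and tMCAO_DE. Per the labels' protocols, total RNA was isolated with a silica column kit and made into paired-end libraries with Illumina's TruSeq RNA kit. The time between occlusion and sampling and the part of the brain taken are not given in the sources used here. Animal identifiers in the labels differ for every library, so libraries were treated as separate animals, and replicate numbers were not taken to pair them.

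The authors deposited 4 tables, 1 per group, each with a count and an FPKM value per gene and library and a mean FPKM per group. The counts, per the file headers, are whole numbers per gene and were deposited without normalisation. The FPKM values deposited by the authors are counts scaled to gene length and library size, and their mean column equalled the mean of the libraries to within 6.7e-06. Per the submitters' processing notes, Cufflinks 2.1.1 and Cuffdiff were used with the mouse build mm10. The aligner, the annotation, the counting tool and whether counting used strand are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart, which concerns Csf1r, Cx3cr1, Hspa1a, Icam1, Il1a, Il1b, Gpr17, Cd180, Selp and P2ry12 among others. Itgam, Lenep, Lilrb4a, Lilr4b, Spp1 and Ube2v1 overlap another gene on the same strand, and Hspa1a and Hspa1b, Lilrb4a and Lilr4b, C4b and Cyp3a57 have close copies, so their counts are uncertain.

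The plan, fixed before the data were examined, foresaw FPKM and named a count test in case the tables held counts. They did, so edgeR's quasi-likelihood test was used on the counts as deposited, and limma on log2 FPKM became an alternative. The design, the lists of genes, the rule for named genes and most alternatives were also set before the data were examined. There were 22110 entries for the sham groups and 22160 for the tMCAO groups, and 21056 genes were in all 4 tables. Genes of only the sham (1002) or only the tMCAO tables (1053) were not tested. Counts of 29 symbols with more than 1 entry were summed, and 24 names that a spreadsheet had turned into dates were left out.

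Total counts were 19261853, 17104926 and 18489058 in sham_CON and 19161585, 22081167, 16658496 and 17627342 in sham_DE. They were 17397616, 20254472, 16240416 and 20419821 in tMCAO_CON and 19521742 and 19616298 in tMCAO_DE, in replicate order. Mitochondrial genes took 7.84% to 8.74% of the counts in depleted and 9.03% to 9.85% in control libraries. Libraries correlated at r = 0.976 to 0.987 within groups and 0.951 to 0.983 between groups, across genes on log2 CPM, and no pair within a group agreed within sampling noise (lowest chi-square per gene 9.02). The genotype labels differ between libraries in the number of the locus that carries the toxin receptor, and were read as 1 genotype, which is an assumption. Replicate 4 of tMCAO_CON was grouped by its title and description although its treatment entry reads sham surgery, and results without it are given.

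Counts were scaled by TMM factors and filtered with filterByExpr for a smallest group of 2, which kept 16940 genes and removed 4116. A single model of 4 group means was fitted over the 13 libraries with edgeR 4.0.16 in R 4.3.3, because tMCAO_DE has only 2. The common biological coefficient of variation was 15.2% and the prior degrees of freedom 4.17. The 5 comparisons were both occlusion contrasts, both depletion contrasts and their interaction, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were obtained as the absolute log2 fold change divided by the square root of F, an approximation. Where a group had no counts, the fold is a lower bound from a floor of 3 counts per library. With 1 to 3 counts in a group, the ratio is given with an exact 95% Poisson interval. Floors and intervals cover counting error only.

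The 44 lists held 572 members, 544 of them in all tables. Each was tested with camera in limma 3.58.1, with a preset correlation of 0.01 on log2 CPM with a prior count of 2, and again with an estimated correlation. In the occlusion comparison with microglia present, the calls of the pan-reactive and A2 astrocyte, activation and p53 lists held with an estimated correlation. No list call described in the other comparisons did. Genes were named by rule, namely 12 genes of the study's axis, up to 10 rises and 10 falls per comparison with separated groups and a mean of at least 1 FPKM, and up to 4 members per described list. Genes were then trimmed in that order, and which lists are described was chosen after their values were seen. A gene that the rule named is counted among the named genes but not reported here. Coordinates come from a GENCODE annotation of GRCm38, the build called mm10. In 226 of 10014 genes above a mean count of 200, counts differed within a group by more than 1.5 on the log2 scale, and 21.1% of these overlapped a same-strand gene, against 8.5% of the others. Among genes named here these were Adamts9, Cbln4, Ctss, Dcn, Fcrls, Hmox1, Itgam, Lcn2, Lypd6, Nr1d1, Selplg, Spp1 and Ube2v1.

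The test was checked on simulated counts with 50 changed genes per fold size. Changed genes were drawn from those above a minimum expected count, all other genes had a common mean, and noise was independent between libraries. The shares below therefore do not cover genes with few counts, or differences between libraries of a group like that of sham_DE 1. In the comparison of tMCAO_CON with sham_CON it recovered 68% of 2-fold and 92% of 4-fold changes and called 9 of 16413 unchanged genes. For tMCAO_DE against sham_DE the shares were 68% and 92%, for sham_DE against sham_CON 72% and 90%, for tMCAO_DE against tMCAO_CON 70% and 94%, and for the interaction 36% and 80%. Alternatives were other filters and scaling, DESeq2 1.42.0, limma with library weights or on log2 FPKM, a replicate block, the compared groups alone and each library left out in turn.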

Results

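RNA from mouse brain was sequenced in 13 libraries to follow the transcriptional response to a transient stroke with microglia present or depleted. Per the labels, the mice carried a tamoxifen-inducible Cre recombinase at the Cx3cr1 gene, which is active in microglia and other mononuclear phagocytes, and a Cre-dependent diphtheria toxin receptor. The toxin at 50 ng per g body weight, given on 3 days starting 30 days after tamoxifen, marked the depleted groups (DE), and saline the control groups (CON). The stroke was a transient occlusion of the middle cerebral artery for 60 min (tMCAO), set against sham surgery. The groups were sham_CON (n = 3), sham_DE (n = 4), tMCAO_CON (n = 4) and tMCAO_DE (n = 2), each library from its own animal. Libraries held 16240416 to 22081167 counts over 21056 genes, of which 16940 were tested. Levels are CPM, counts scaled to the TMM-adjusted library total, as mean ± SD over the libraries of a group. Changes are log2 fold changes ± the standard error of the fitted coefficient, with adjusted p from edgeR's quasi-likelihood test. Replicate 4 of tMCAO_CON carried a treatment entry of sham surgery, against its title and description, and was kept in the group of its title. On the second principal component it lay at -22.4, against -38.4 to -20 for the other tMCAO_CON libraries and 16 to 35.1 for the sham libraries.

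The depletion was checked first, in every library. Csf1r, the receptor for colony-stimulating factor 1 on which microglia depend, lay between 92 and 93.4 CPM in sham_CON and between 76.4 and 97.4 CPM in tMCAO_CON. It lay between 6.1 and 16 CPM in sham_DE and between 6.08 and 8.51 CPM in tMCAO_DE. Tmem119, a surface protein of homeostatic microglia, averaged 17.2 ± 1.24 CPM in sham_CON, 1.26 ± 0.972 in sham_DE, 15.5 ± 2.15 in tMCAO_CON and 0.832 ± 0.0405 in tMCAO_DE. Cx3cr1, the fractalkine receptor and the locus of the Cre allele, had few counts, namely 21, 404 and 21 in sham_CON, 26, 27, 5 and 0 in sham_DE, 34, 22, 18 and 43 in tMCAO_CON and 0 and 1 in tMCAO_DE. Outside the library with 404, sham_CON counts of Cx3cr1 lay within the range of sham_DE, whereas Csf1r was alike in all sham_CON libraries. Cx3cr1 therefore did not measure the depletion in sham mice. On the mouse build GRCm38 (mm10), Csf1r lies on chromosome 18 from 61100598 to 61132149 with 24 exon blocks, Tmem119 on chromosome 5 from 113793729 to 113800516 with 3 and Cx3cr1 on chromosome 9 from 119901616 to 120069879 with 4.

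**Figure D1:**
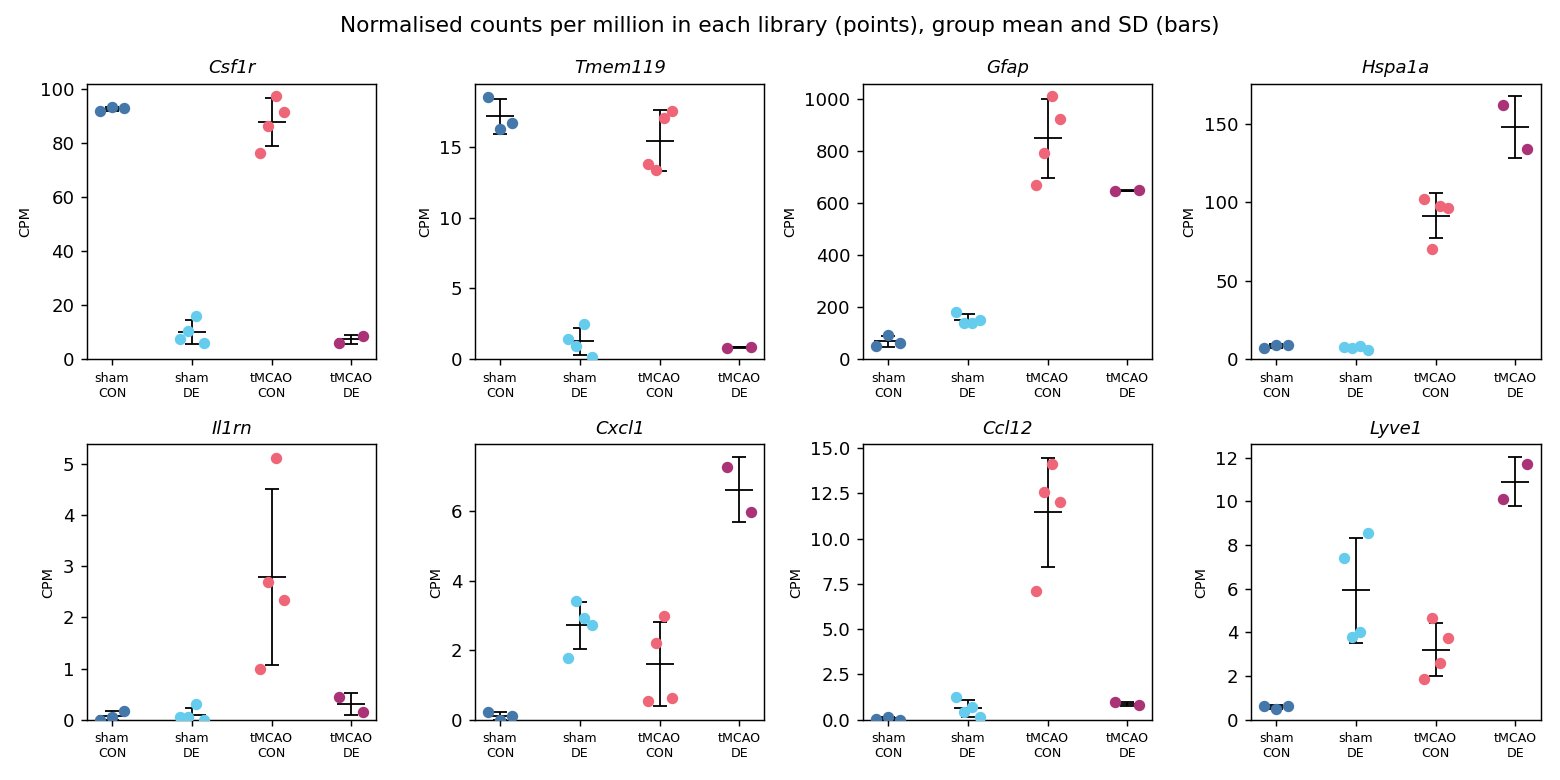
Normalised expression in CPM of 8 genes in the 13 libraries, 1 panel per gene, with each library as a point and the group mean ± SD as bars. Csf1r and Tmem119 were low in every depleted library, Gfap and Hspa1a were high after occlusion in both treatment groups, and Il1rn and Ccl12 were high in tMCAO_CON alone, at means of 2.78 and 11.4 CPM.

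The sham_DE (n = 4) and sham_CON (n = 3) groups were compared to describe the brain without microglia and without stroke. Csf1r fell from 92.7 ± 0.718 to 9.96 ± 4.35 CPM (log2 fold change -3.22 ± 0.24, edgeR adjusted p = 4.1e-05), and C1qa, a subunit of the first complement component, from 34.1 ± 5.03 to 8.81 ± 2.12 CPM (-1.95 ± 0.15, edgeR adjusted p = 4.1e-05). Lyve1, a hyaluronan receptor of border-associated macrophages and lymphatic vessels, rose from 0.581 ± 0.0896 to 5.94 ± 2.4 CPM (3.33 ± 0.41, edgeR adjusted p = 0.00076). Cxcl1, a chemokine that attracts neutrophils, rose from 0.109 ± 0.107 to 2.71 ± 0.682 CPM (4.51 ± 0.76, edgeR adjusted p = 0.0057). Gfap, the intermediate filament of astrocytes, rose from 68.6 ± 20.7 to 151 ± 19.8 CPM (1.14 ± 0.18, edgeR adjusted p = 0.0044).

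Among the other genes of the interleukin-1 and neutrophil axis, Icam1, an adhesion molecule for leukocytes, rose by 2.39 ± 0.32 (edgeR adjusted p = 0.0013). The log2 change of Il1a, encoding interleukin-1 alpha, was -3.37 ± 0.68 (edgeR adjusted p = 0.011) and that of Cx3cr1 -3.52 (95% interval -5.69 to -1.35, edgeR adjusted p = 0.04). Most sham_CON counts of Cx3cr1 lay in replicate 2, so the size of its change rests on that library. The Cx3cr1 call ended without sham_CON replicate 2 (edgeR adjusted p = 0.66), and also without any of sham_DE replicates 2, 3 and 4, the 4 tMCAO_CON libraries or either tMCAO_DE library. Il1rn, encoding the interleukin-1 receptor antagonist, changed by 0.31 ± 1.30 (edgeR adjusted p = 0.91), Il1b by 1.08 ± 0.50 (0.18), Il1r1 by -0.13 ± 0.27 (0.79), Cxcl2 by 1.64 ± 0.81 (0.2) and the neutrophil peroxidase Mpo by 1.94 ± 1.12 (0.27), none past the test. Cxcr2, the receptor for Cxcl1 and Cxcl2, had too few counts in both groups for a fold, and Ly6g, a neutrophil surface marker, had too few to be tested in any comparison. As a list, the axis had 3 higher and 2 lower of 11 tested, the same when adjusted over the list alone (camera adjusted p = 0.092, and 0.012 without sham_CON 2 or 0.049 without sham_DE 4).

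Homeostatic microglia genes fell in 20 of 20 tested members, and 20 when adjusted over the list alone (camera adjusted p = 1.3e-25, adjusted p = 0.08 with an estimated correlation), with a median log2 change of -2.26. Examples were Tmem119 at -3.79 ± 0.38, the purinergic receptors P2ry12 at -3.78 ± 0.45 and P2ry13 at -3.35 ± 0.36, Selplg at -3.70 ± 0.37 and Gpr34 at -3.44 ± 0.45. Csf3r, the receptor for granulocyte colony-stimulating factor, Lag3 and Crybb1 fell with them, at -4.01 ± 0.47, -3.52 ± 0.45 and -3.36 ± 0.33. Microglia and macrophage activation genes went both ways, with 7 higher and 3 lower of 20, and 8 and 4 when adjusted over the list alone (camera adjusted p = 0.093). That list's test passed without sham_DE replicate 4 (camera adjusted p = 0.046). Its risen members included Lyve1, the scavenger receptor Cd163 at 2.98 ± 0.38 and the platelet factor Pf4 at 1.83 ± 0.40, and its fallen members the lysosomal protease Ctss at -3.38 ± 0.38. Outside the list, the coagulation factor F13a1 at 2.42 ± 0.25 and the folate receptor Folr2 with a count ratio of 29.9 (95% counting interval 8.03 to 251), rose as well. The complement list had 2 higher and 4 lower of 13, and 3 and 4 when adjusted over the list alone (camera adjusted p = 0.14, and 0.039 without sham_CON replicate 1 or 0.025 without sham_DE replicate 3). Its members included C3 at 2.42 ± 0.56, C1qb at -1.94 ± 0.22 and the integrin Itgam, which overlaps a same-strand gene, at -2.12 ± 0.27.

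Genes of cholesterol synthesis fell in 8 of 15 members, 11 when adjusted over the list alone (camera adjusted p = 0.00011, adjusted p = 0.63 with an estimated correlation), among them Msmo1 at -0.87 ± 0.23. Oligodendrocyte precursor genes fell in 3 of 8, 4 when adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.08 with an estimated correlation), with Bcas1 at -0.94 ± 0.16 and Gpr17, a receptor of committed precursors, at -0.67 ± 0.11. Cell cycle genes rose in 5 of 17, 6 when adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.63 with an estimated correlation). Examples were the proliferation marker Mki67 at 1.79 ± 0.53 and the cyclin-dependent kinase Cdk1 at a count ratio of 13.5 (95% counting interval 3.5 to 116). The neutrophil list had 1 member higher and 2 lower of 13, the same numbers adjusted over the list alone (camera adjusted p = 0.88), the fallen ones being Csf3r and Itgam. S100a8 and S100a9, calgranulins abundant in neutrophils that were chosen after their values were seen, stood apart in sham_CON replicate 2 at 8.49 and 15.6 CPM and in sham_DE replicate 3 at 8.11 and 16.5 CPM, against at most 1.76 CPM of S100a8 in every other library. S100a9 was at 6.18 CPM in tMCAO_DE replicate 1 and at most 2.06 CPM in the rest.

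The largest rises among genes with separated groups were in transcripts low in the brain. They included the serine protease Tmprss9 at 6.25 ± 1.02, Misp at 5.75 ± 1.07, Gucy2c, the intestinal guanylate cyclase, at 5.45 ± 0.88 and Muc2, the intestinal mucin, at 4.21 ± 0.81. Also in this set were Loxhd1, a gene of hair cells of the ear, at 5.58 ± 0.76, Cfap53 at 4.79 ± 0.80, Pde6b, a phosphodiesterase of photoreceptors, at 4.25 ± 0.75, A3galt2 at 4.05 ± 0.66 and Nmrk2 at 4.02 ± 0.74. Loxhd1 averaged 11 ± 7.43 CPM in sham_DE, and Muc2 12.4 ± 10.6. Summed over Muc2, Gucy2c, Duox2 and Ctrb1, levels were 2.16 CPM in sham_DE replicate 1 and 21.9 to 41 CPM in the other 3 sham_DE libraries. They were 0.376 to 1.24 CPM in sham_CON and 1.7 to 2.93 CPM in tMCAO_CON. The rise of these genes thus rested mostly on those 3 libraries, although Csf1r was low in replicate 1 as well. Over the 1960 genes with under 0.05 CPM in sham_CON, summed levels were 95.2 CPM in sham_DE replicate 1 and 237 to 276.5 CPM in the other 3 sham_DE libraries, against 127.5 to 190.9 CPM in tMCAO_CON. Mitochondrial genes took 7.84% to 8.74% of the counts in the 6 depleted libraries and 9.03% to 9.85% in the 7 control libraries, a separation that held for sham and occluded mice alike.

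In all, 1921 genes passed the threshold between sham_DE and sham_CON, 1161 higher and 760 lower, of which 383 and 172 changed by at least 2-fold. The number was 611, 821 and 591 without sham_CON replicates 1, 2 and 3, and 3725, 747, 1104 and 670 without sham_DE replicates 1, 2, 3 and 4. Without sham_CON replicate 2 and sham_DE replicate 3 together, the pair with high S100a8, 219 genes passed, 82 higher and 137 lower, and 212 of them also passed with all libraries. Among named genes, that removal ended the calls of Cx3cr1 (edgeR adjusted p = 0.82), Il1a, Cxcl1, Misp, Cfap53, Folr2, Muc2, Nmrk2, Pf4, Bcas1, Msmo1, Ccl2, C3, Cdk1 and Mki67 (edgeR adjusted p = 0.05 to 0.12). Fewer libraries also lower the power of the test, and no other pair was left out for comparison. The drop therefore cannot be credited to this pair in particular. Hemoglobin counts were 497 and 519 in the pair and 16 to 205 in the other sham libraries. They were highest, at 627, in tMCAO_CON replicate 1, where S100a8 was at 0.552 CPM. The first principal component held 32.6% of the variance. On it sham_DE replicate 1 lay at -5, the other depleted libraries at 31.9 to 48 and the controls at -34.6 to -20.7. Loss of microglia alone did not set this position, since Csf1r in sham_DE replicate 1 was at 7.57 CPM, within the range of the depleted libraries. That library correlated at r = 0.98 to 0.983 with the sham_CON libraries and at 0.976 to 0.978 with the other sham_DE libraries. Calls that ended without a library were Pf4 (edgeR adjusted p up to 0.064, sham_CON replicates 1 and 3), Msmo1 (0.12, sham_CON 1 and 3 and sham_DE 2, 3 and 4) and Ccl2, which had risen by 3.20 ± 0.74 (0.06, each sham_CON library). They also ended for C3 (0.076, sham_CON 2 and 3 and sham_DE 2), Cdk1 (0.095, sham_CON 2 and 3 and sham_DE 4) and Mki67 (0.15, each sham library, tMCAO_CON 1 and 2 and both tMCAO_DE).

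The response to stroke with microglia present was read from tMCAO_CON (n = 4) against sham_CON (n = 3). Gfap rose from 68.6 ± 20.7 to 848 ± 151 CPM (log2 fold change 3.63 ± 0.20, edgeR adjusted p = 1.2e-06), and Hspa1a, an inducible heat shock chaperone, from 8.27 ± 1.08 to 91.5 ± 14.3 CPM (3.47 ± 0.16, edgeR adjusted p = 2e-07). Il1rn rose from 0.0764 ± 0.0859 to 2.78 ± 1.72 CPM (5.08 ± 0.87, edgeR adjusted p = 0.0039), and Cxcl1 from 0.109 ± 0.107 to 1.6 ± 1.21 CPM (3.74 ± 0.80, edgeR adjusted p = 0.013). Ccl12, a chemokine for monocytes, rose from 0.0777 ± 0.0921 to 11.4 ± 3.02 CPM (7.12 ± 0.63, edgeR adjusted p = 3.6e-05). Egr1, a transcription factor induced by neuronal activity, fell from 437 ± 59.4 to 157 ± 35.6 CPM (-1.48 ± 0.23, edgeR adjusted p = 0.0025). On GRCm38, Gfap lies on chromosome 11 from 102887336 to 102900912, Hspa1a on chromosome 17 from 34969190 to 34972156, Il1rn on chromosome 2 from 24336853 to 24351494 with 6 exon blocks and Cxcl1 on chromosome 5 from 90891241 to 90893115.

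Of the remaining axis genes, Il1b rose by 1.74 ± 0.48 (edgeR adjusted p = 0.042), Il1r1, the signalling receptor of interleukin-1, by 1.27 ± 0.26 (0.011) and Icam1 by 1.73 ± 0.32 (0.0063). Cx3cr1 at -2.52 ± 0.93 (0.12), Il1a at 1.25 ± 0.45 (0.11), Cxcl2 at 0.89 ± 0.85 (0.58), Mpo at -2.00 ± 1.63 (0.5) and Cxcr2 (0.3) did not pass. Most sham_CON counts of Cx3cr1 lay in sham_CON 2, so the size of its change rests on that library. The Il1b call ended, with adjusted p up to 0.16, without sham_CON 1 or 3, sham_DE 2, 3 or 4 or any tMCAO_CON library. The Il1r1 call ended without sham_CON 1 (0.056) and the Cxcl1 call without sham_CON 3 (0.06) or without sham_CON 2 and sham_DE 3 together (0.058). As a list, axis genes rose in 6 of 11, and 7 with 1 lower when adjusted over the list alone (camera adjusted p = 2.2e-05, adjusted p = 0.11 with an estimated correlation).

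Pan-reactive astrocyte genes rose in 12 of 13 members, 12 when adjusted over the list alone (camera adjusted p = 2.3e-18, adjusted p = 0.028 with an estimated correlation). Among them were the protease inhibitors Timp1 at 4.77 ± 0.73 and Serpina3n at 3.85 ± 0.25, the interferon-induced chemokine Cxcl10 at 4.48 ± 0.69 and the lipocalin Lcn2 at 3.94 ± 0.63. In the set of astrocyte genes named A2 in earlier work, Ptx3 rose by 5.73 ± 0.93, Tgm1 by 6.89 (95% interval 4.73 to 9.04) and Slc10a6 at least 14.1-fold from no counts. That set had 10 of 12 members higher, 11 when adjusted over the list alone (camera adjusted p = 1.2e-10, adjusted p = 0.033 with an estimated correlation). Microglia and macrophage activation genes rose in 13 of 20, and 16 with 1 lower when adjusted over the list alone (camera adjusted p = 5.3e-13, adjusted p = 0.028 with an estimated correlation). Examples were the scavenger receptor Msr1 at 5.90 ± 0.54, the galectin Lgals3 at 4.61 ± 0.46 and the secreted phosphoprotein Spp1 at 4.56 ± 0.37. Homeostatic microglia genes were higher in 5 of 20 and lower in none, the same when adjusted over the list alone (camera adjusted p = 0.27), the 5 including Fcrls and the C1q genes, with C1qa at 59.6 ± 1.8 against 34.1 ± 5.03 CPM.

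Interferon response genes rose in 16 of 20, 19 when adjusted over the list alone (camera adjusted p = 5.3e-13, adjusted p = 0.13 with an estimated correlation). They included the antiviral genes Mx1 at 2.99 ± 0.55 and Rsad2 at 2.55 ± 0.48. Cytokine and NF-kB response genes rose in 14 of 18, 16 when adjusted over the list alone (camera adjusted p = 5.3e-13, adjusted p = 0.077 with an estimated correlation). Among these were the monocyte chemokine Ccl2 at 4.96 ± 0.67 and tumour necrosis factor, Tnf, at a count ratio of 44.3 (95% counting interval 7.68 to 1780). Heat shock genes rose in 8 of 12, 8 when adjusted over the list alone (camera adjusted p = 4.2e-08, adjusted p = 0.1 with an estimated correlation), with Hspa1b, a near-identical copy of Hspa1a, at 3.60 ± 0.23. Complement genes rose in 9 of 13, 10 when adjusted over the list alone (camera adjusted p = 1e-08, adjusted p = 0.11 with an estimated correlation). They included the C5a receptor C5ar1 at 3.42 ± 0.38 and C4b, which has a close paralog, at 3.03 ± 0.28. Endothelial adhesion and activation genes rose in 7 of 12, 9 when adjusted over the list alone (camera adjusted p = 2.2e-07, adjusted p = 0.11 with an estimated correlation). Among these were the selectins Selp at least 11.7-fold from no counts and Sele at a ratio of 49.9 (13.6 to 416). General neuronal genes fell in 4 of 12, 6 when adjusted over the list alone (camera adjusted p = 0.00017, adjusted p = 0.13 with an estimated correlation). Examples were the synaptic proteins Snap25 at -0.34 ± 0.06 and Syp at -0.34 ± 0.07.

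Immediate early genes were 2 higher and 5 lower of 16, 3 and 9 when adjusted over the list alone (camera adjusted p = 0.0041, adjusted p = 0.34 with an estimated correlation). Members past the test included Fosl1 at a ratio of 62 (16.9 to 516), Egr4 at -1.31 ± 0.25 and Nr4a1 at -1.31 ± 0.28. Of the largest rises, Mmp3, the protease stromelysin, was at least 31.3-fold higher than the floor of no counts in sham_CON, and macrophage elastase Mmp12 had a ratio of 89.7 (24.6 to 745). The leukocyte receptor Lilrb4a rose by 5.16 ± 0.38, while its adjacent paralog Lilr4b, with which it can share reads, had a ratio of 143 (39.4 to 1190) and the receptor Hcar2 58.2 (15.9 to 484). The cell cycle inhibitor Cdkn1a rose by 1.90 ± 0.30. Among falls were Lypd6 at -2.28 ± 0.51, Pja1 at -1.40 ± 0.27, the neuronal chemokine Cx3cl1 at -1.24 ± 0.26, Ankrd63 at -1.23 ± 0.19, Crybb1 at -1.18 ± 0.27 and the synaptic organiser Cbln2 at -1.17 ± 0.19. By edgeR's quasi-likelihood test, calls ended without a library for Lypd6 (adjusted p = 0.053, sham_CON 3), Cx3cl1 (0.054, sham_CON 1), Crybb1 (0.085, sham_CON 1 or 3) and Syp (0.059, sham_CON 1).

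After occlusion with microglia present, 1430 genes passed, 870 higher and 560 lower, of which 432 and 33 changed by at least 2-fold. On log2 FPKM with a pseudocount of 1, a scaling with no further normalisation, 82.7% of called genes were higher, against 60.8% here. The count was 666 and 564 without sham_CON replicates 1 and 3, and 935 without tMCAO_CON replicate 3. It was 954 without sham_CON replicate 2 and sham_DE replicate 3, and 1241 without tMCAO_CON replicate 4, the library with the conflicting label.

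The response to stroke after depletion was read from tMCAO_DE (n = 2) against sham_DE (n = 4). Gfap rose from 151 ± 19.8 to 647 ± 1.39 CPM (log2 fold change 2.09 ± 0.19, edgeR adjusted p = 7.1e-05). Hspa1a rose 20.6-fold from 7.19 ± 0.981 CPM (4.37 ± 0.16, edgeR adjusted p = 8.6e-09) and Hspa1b by 4.49 ± 0.22. Mmp3 rose from 0.162 ± 0.222 to 8.46 ± 5.58 CPM (5.65 ± 0.98, edgeR adjusted p = 0.0055). Gpr17 fell from 34.2 ± 3.51 to 11.4 ± 0.851 CPM (-1.58 ± 0.15, edgeR adjusted p = 7.1e-05).

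Il1r1 was the other axis gene past the test, at 1.43 ± 0.28 (edgeR adjusted p = 0.0069). Il1rn at 1.60 ± 1.08 (edgeR adjusted p = 0.36), Cxcl1 at 1.28 ± 0.50 (0.11), Il1a at 2.57 ± 0.80 (0.052) did not pass. Neither did Il1b at -0.04 ± 0.50 (0.97), Cxcl2 at 0.57 ± 0.74 (0.66), Icam1 at 0.00 ± 0.31 (1) or Mpo at -0.40 ± 1.07 (0.84). Cxcr2 had a higher-to-lower count ratio of 12.5 (95% counting interval 3.71 to 65.8, edgeR adjusted p = 0.14), and Cx3cr1, with fewer counts after occlusion, 30.9 (5.33 to 1240, edgeR adjusted p = 0.28). Il1a passed without sham_DE replicate 3 or tMCAO_DE replicate 2 (lowest 0.035), and the Il1r1 call ended without either tMCAO_DE library (up to 0.059). The axis list had 2 of 11 higher, 3 when adjusted over the list alone (camera adjusted p = 0.032, adjusted p = 0.48 with an estimated correlation). Its test ended without sham_DE 4 (camera adjusted p = 0.075), tMCAO_CON 3 (0.052) or tMCAO_DE 1 (0.21).

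Pan-reactive astrocyte genes rose in 11 of 13, 11 when adjusted over the list alone (camera adjusted p = 1e-10, adjusted p = 0.077 with an estimated correlation). Examples were Lcn2 at 4.06 ± 0.56, Timp1 at 3.92 ± 0.64 and Serpina3n at 3.37 ± 0.24. Heat shock genes rose in 9 of 12, 9 when adjusted over the list alone (camera adjusted p = 1.9e-10, adjusted p = 0.077 with an estimated correlation). The A2 astrocyte set rose in 7 of 12, 10 when adjusted over the list alone (camera adjusted p = 2.3e-08, adjusted p = 0.077 with an estimated correlation). Among them were the bile acid transporter family member Slc10a6 at 6.01 ± 0.72, Tgm1 at 4.20 ± 0.75, Ptx3 at 3.92 ± 0.75 and the lipopolysaccharide co-receptor Cd14 at 2.95 ± 0.65. Interferon response genes rose in 10 of 20, 16 when adjusted over the list alone (camera adjusted p = 1.1e-08, adjusted p = 0.33 with an estimated correlation). They included the guanosine triphosphatases Irgm1 at 2.55 ± 0.23 and Gbp2 at 2.33 ± 0.50. Cytokine and NF-kB response genes rose in 10 of 18, 10 when adjusted over the list alone (camera adjusted p = 1e-05, adjusted p = 0.3 with an estimated correlation), with interleukin-6, Il6, at a count ratio of 67.6 (11.4 to 2740). Endothelial adhesion genes rose in 7 of 12, 8 when adjusted over the list alone (camera adjusted p = 0.0017, adjusted p = 0.33 with an estimated correlation), with Sele at 2.88 ± 0.63 and Selp at a ratio of 31.9 (8.18 to 274).

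Activation genes of microglia and macrophages rose in 6 of 20, and 8 with 1 lower when adjusted over the list alone (camera adjusted p = 0.0047, adjusted p = 0.33 with an estimated correlation), with Spp1 at 2.50 ± 0.35. No homeostatic microglia gene passed, over all genes or over the list alone (camera adjusted p = 0.33, and 0.027 without sham_DE replicate 3). Arginase, Arg1, rose by 4.46 ± 0.79, the protease Adamts9 16-fold (95% interval of the log2 change 2.99 to 5.02), heme oxygenase Hmox1 by 3.56 ± 0.38 and hexokinase Hk2 by 1.68 ± 0.23. Falls included Ube2v1 at -2.87 ± 0.78, Egr2 at -2.64 ± 0.67, the endothelial gene Itm2a at -1.81 ± 0.37, and Tnfrsf25 at -1.73 ± 0.43. Also lower were the phospholipid transfer protein Pltp at -1.70 ± 0.47, Syt10 at -1.65 ± 0.33, Cbln4 at -1.59 ± 0.48, the matrix proteoglycan Prelp at -1.58 ± 0.35 and Ankrd63 at -1.57 ± 0.24. Counts of Adamts9, Hmox1, Ube2v1 and Cbln4 differed within a group by more than 1.5 on the log2 scale.

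After occlusion of depleted mice, 2106 genes passed, 1116 higher and 990 lower, of which 358 and 119 changed by at least 2-fold. Leaving out tMCAO_DE replicate 1 gave 523 and replicate 2 gave 453, the lone library then being assumed to vary like the other groups. Without sham_CON replicate 2 and sham_DE replicate 3 the count was 1566, and the calls of Ube2v1 (edgeR adjusted p = 0.051) and Cbln4 (0.079) ended. On log2 FPKM with a pseudocount of 1, 63.4% of called genes were higher, against 53% here. By edgeR's quasi-likelihood test, calls ended without tMCAO_DE 2 for Mmp3 (adjusted p = 0.057), Arg1 (0.099), Syt10 (0.11), Prelp (0.15) and Gbp2 (0.17). Without either tMCAO_DE library they ended for Egr2 (up to 0.17), Itm2a (0.11), Tnfrsf25 (0.14), Il6 (0.075), Cd14 (0.1) and Sele (0.11), and without these or sham_DE 2 for Ube2v1 (0.19) and Selp (0.14). Pltp was lost (up to 0.21) without sham_DE 1 or 2 or either tMCAO_DE library, and Cbln4 (up to 0.27) without any sham_CON library, sham_DE 1 or 3, tMCAO_CON 3 or 4 or either tMCAO_DE library.

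The occlusion comparisons with and without microglia shared no library, only the estimate of the spread. Of the genes called, 431 were higher in both, against 57.3 for independent lists, 278 were lower in both, against 32.7, and 3 went opposite ways. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.48.

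The effect of depletion after stroke was read from tMCAO_DE (n = 2) against tMCAO_CON (n = 4). Il1rn fell from 2.78 ± 1.72 to 0.302 ± 0.212 CPM (log2 fold change -3.17 ± 0.81, edgeR adjusted p = 0.019), and Cxcl1 rose from 1.6 ± 1.21 to 6.63 ± 0.924 CPM (2.06 ± 0.51, edgeR adjusted p = 0.016). Ccl12 fell from 11.4 ± 3.02 to 0.882 ± 0.102 CPM (-3.69 ± 0.51, edgeR adjusted p = 0.0013), and Cd180, a Toll-like receptor homologue, from 12.6 ± 3.81 to 0.732 ± 0.254 CPM (-4.09 ± 0.34, edgeR adjusted p = 3.6e-05). Gpr17 fell from 32.3 ± 4.87 to 11.4 ± 0.851 CPM (-1.49 ± 0.14, edgeR adjusted p = 0.00014). Gfap was at 848 ± 151 and 647 ± 1.39 CPM (-0.39 ± 0.20, edgeR adjusted p = 0.19), not past the test. Both tMCAO_DE libraries were needed for the calls of Il1rn, which reached an adjusted p of 0.17, and Cxcl1, 0.096, when either was left out.

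Il1a changed by -2.06 ± 0.57 (edgeR adjusted p = 0.025, and 0.23 without tMCAO_DE 2). Il1b at -0.70 ± 0.49 (edgeR adjusted p = 0.33), Il1r1 at 0.03 ± 0.28 (0.96), Cxcl2 at 1.31 ± 0.76 (0.24), Icam1 at 0.66 ± 0.31 (0.15), Cxcr2 at 1.73 ± 1.17 (0.32) and Mpo at 3.54 ± 1.47 (0.11) did not pass. Cx3cr1, with 0 and 1 counts in tMCAO_DE, had a count ratio of 60.6 (95% counting interval 10.7 to 2410, edgeR adjusted p = 0.12), and passed without sham_CON replicate 2 (0.02). The neutrophil list had 2 members lower of 13, 2 when adjusted over the list alone (camera adjusted p = 0.68), Csf3r and Itgam. Both had also fallen with the homeostatic microglia genes in depleted sham mice, by -4.01 ± 0.47 and -2.12 ± 0.27. Their fall here is therefore no measure of neutrophils. The axis list had 1 higher and 2 lower of 11, the same when adjusted over the list alone (camera adjusted p = 0.97).

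Homeostatic microglia genes fell in 19 of 20, 20 when adjusted over the list alone (camera adjusted p = 1.8e-18, adjusted p = 0.17 with an estimated correlation). Examples were P2ry13 at -4.37 ± 0.49, Fcrls at -4.25 ± 0.44, Tmem119 at -4.21 ± 0.51 and Gpr34 at -4.18 ± 0.64. Complement genes fell in 7 of 13, 7 with 1 higher when adjusted over the list alone (camera adjusted p = 0.0046, adjusted p = 1 with an estimated correlation), with C1qb at -2.72 ± 0.28 and C1qa at -2.51 ± 0.19. Oligodendrocyte precursor genes fell in 4 of 8, 4 when adjusted over the list alone (camera adjusted p = 0.0097, adjusted p = 0.17 with an estimated correlation), with the transcription factor Olig1 at -0.58 ± 0.11. Interleukin-1 family genes fell in 4 of 14, 5 when adjusted over the list alone (camera adjusted p = 0.034, adjusted p = 1 with an estimated correlation), among them the inflammasome sensor Nlrp3 at -1.96 ± 0.62. That list's test ended without tMCAO_CON 3 (camera adjusted p = 0.059) or tMCAO_DE 2 (0.13). Cholesterol synthesis genes were 5 lower and 1 higher of 15, 9 and 1 when adjusted over the list alone (camera adjusted p = 0.035, adjusted p = 1 with an estimated correlation), with Sqle at -0.86 ± 0.23. That test ended without tMCAO_CON 2 (camera adjusted p = 0.061), tMCAO_CON 3 (0.059) or tMCAO_DE 2 (0.13). General neuronal genes did not pass as a list (camera adjusted p = 0.11), with 4 lower and 1 higher of 12, and 6 and 1 when adjusted over the list alone, among them the neurofilament Nefl at -0.77 ± 0.17 and Stmn2 at -0.65 ± 0.14. Pan-reactive astrocyte genes were higher in 1 of 13, the same when adjusted over the list alone (camera adjusted p = 0.99).

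Other falls were Ly86 at -4.23 ± 0.63, Bin2 at -4.03 ± 0.51, Hcar2 at -3.79 ± 0.73, the chemokine Ccl3 at -3.50 ± 0.62 and Ctss at -3.30 ± 0.48. Lenep, whose exon overlaps a same-strand gene, was lower with a count ratio of 37.8 (10.3 to 315). Rises included the oxidase Duox2 at 5.26 ± 1.06, Loxhd1 at 4.16 ± 0.62, and Igfbp1 at 3.91 ± 0.67. Also higher were Cyp3a57, which has close paralogs, at 3.59 ± 0.80, Cfap53 at 3.58 ± 0.68, Psca at 3.52 ± 0.77, Tmprss9 at 3.47 ± 0.77, Cym at 3.22 ± 0.77, Smtnl2 at 3.18 ± 0.36 and the potassium channel Kcna10 at 3.15 ± 0.85. Arg1 rose by 2.98 ± 0.68, the chemokine Ccl17 4.3-fold (95% interval of the log2 change 1.08 to 3.13), F13a1 by 1.31 ± 0.24, Hspa1b by 0.75 ± 0.21 and Hspa1a by 0.70 ± 0.15.

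Between the occluded groups, 3155 genes passed, 1586 higher and 1569 lower, of which 318 and 412 changed by at least 2-fold. The count was 1097 without tMCAO_DE replicate 1, 346 without replicate 2 and 2707 without sham_CON replicate 2 and sham_DE replicate 3. On log2 FPKM with a pseudocount of 0.1, 40% of called genes were higher, against 50.3% here. By edgeR's quasi-likelihood test, calls ended without tMCAO_DE 2 for Duox2 (adjusted p = 0.051), Igfbp1 (0.052), Cyp3a57 (0.095), Cfap53 (0.051), Psca (0.088), Tmprss9 (0.078), Hcar2 (0.085), Arg1 (0.27), F13a1 (0.077), Ccl17 (0.098) and Nefl (0.12), and without tMCAO_DE 1 for Hspa1a (0.095). They ended without either tMCAO_DE library for Cym (up to 0.092), Olig1 (0.061), Sqle (0.16) and Stmn2 (0.091), without these or tMCAO_CON 4 for Kcna10 (0.15), and without these or tMCAO_CON 3 for Lenep (0.18) and Hspa1b (0.17). Nlrp3 was lost without sham_CON 2 and sham_DE 3 together (0.065), and (up to 0.21) without any sham_CON library, sham_DE 3 or 4, tMCAO_CON 1, 3 or 4 or either tMCAO_DE library. The depletion comparisons in sham and in occluded brains shared no library. In both, 605 genes were higher, against 108.7 for independent lists, and 422 lower, against 70.4, with 10 opposite. The genes are not independent replicates.

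**Figure D2:**
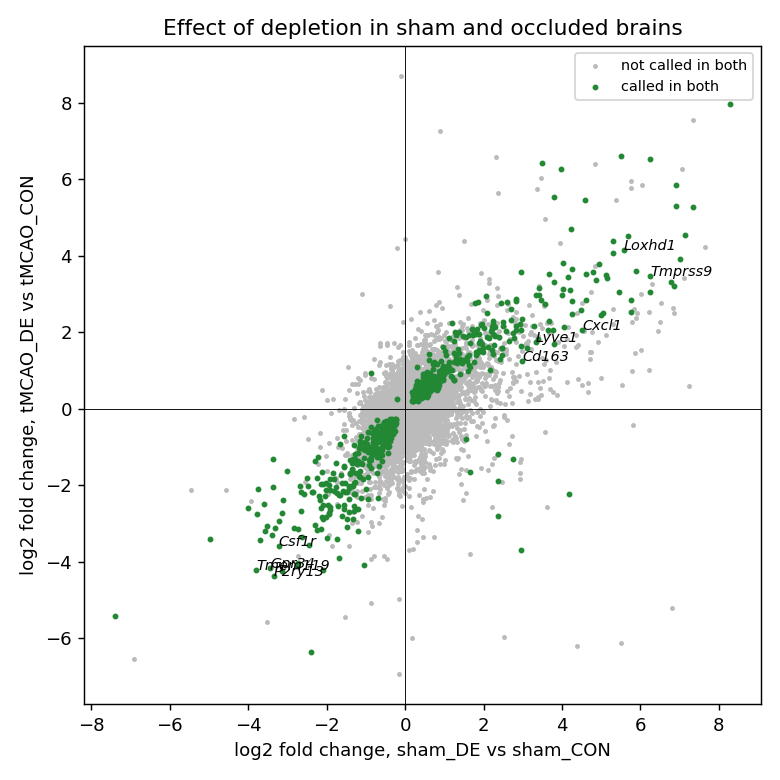
Log2 fold change of each tested gene between sham_DE and sham_CON on the horizontal axis and between tMCAO_DE and tMCAO_CON on the vertical axis, with genes called in both in green. The 605 genes higher in both and 422 lower in both lie in the upper right and lower left, and the correlation across genes was 0.63.

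**Figure D3:**
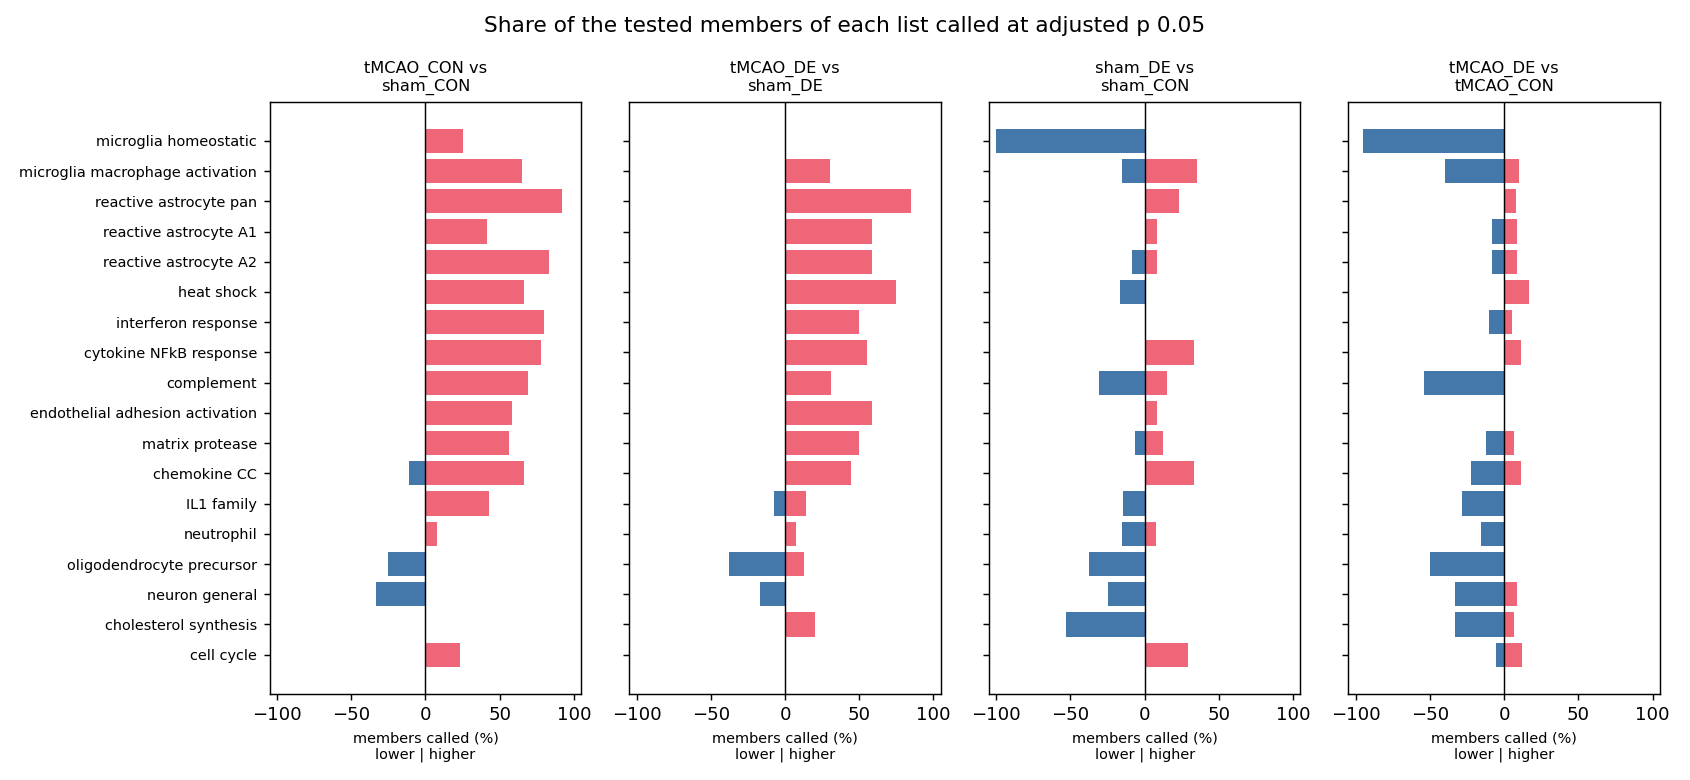
Percentage of the tested members of 18 gene lists called higher (red, to the right) or lower (blue, to the left) in each of 4 comparisons at an adjusted p of 0.05. Homeostatic microglia genes were lower in 20 of 20 and 19 of 20 members in the depletion comparisons, and pan-reactive astrocyte genes higher in 12 of 13 and 11 of 13 in the occlusion comparisons.

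Whether the response to stroke differed with depletion was tested as an interaction, the occlusion change in depleted mice minus that in controls. In 7 genes the occlusion change was lower in depleted mice. Ccl12 (-6.65 ± 0.93, edgeR adjusted p = 0.028) went from 0.0777 ± 0.0921 to 11.4 ± 3.02 CPM in controls and from 0.639 ± 0.464 to 0.882 ± 0.102 CPM in depleted mice. Lilrb4a (-4.08 ± 0.51, edgeR adjusted p = 0.019) went from 0.208 ± 0.0654 to 7.66 ± 2.45 and from 1.43 ± 0.359 to 3.05 ± 0.232 CPM. Lipoprotein lipase, Lpl (-2.18 ± 0.31, edgeR adjusted p = 0.028), went from 11.5 ± 3.14 to 32.8 ± 5.15 and from 12.3 ± 3.05 to 7.81 ± 0.597 CPM. Lilr4b had 2 counts in sham_CON, so its fitted interaction of -6.41 (edgeR adjusted p = 0.028) rests on a control ratio with a 95% counting interval of 39.4 to 1190 and is no exact size. Cd180 at -3.06 ± 0.44 (edgeR adjusted p = 0.028) and the endosomal receptor Tlr13 at -1.64 ± 0.25 (0.036) belonged to the same set. Yipf6, a Golgi membrane protein on the X chromosome from 98936316 to 98949017, was at 44.2 ± 0.319 and 50.4 ± 0.931 CPM in controls and 42.5 ± 3.25 and 17 ± 1.79 CPM in depleted mice (-1.51 ± 0.12, edgeR adjusted p = 0.00014). Lingo3 was the gene with a higher change, at 0.80 ± 0.12 (edgeR adjusted p = 0.04).

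No axis gene passed the interaction test over all genes, and 2 of 11, Gfap and Icam1, were lower when adjusted over the list alone (camera adjusted p = 0.041, adjusted p = 0.77 with an estimated correlation). The list test ended without sham_CON 1 (camera adjusted p = 0.095) or 3 (0.074), sham_DE 1 (0.075), 2 (0.06) or 3 (0.052), tMCAO_CON 2 (0.069) or tMCAO_DE 2 (0.29). Gfap was at -1.53 ± 0.27 (edgeR adjusted p = 0.089, and 0.037 without sham_CON replicate 2), Il1rn at -3.48 ± 1.59 (0.51), Cxcl1 at -2.45 ± 1.01 (0.47), Il1b at -1.78 ± 0.70 (0.45) and Icam1 at -1.73 ± 0.45 (0.25). Activation genes of microglia and macrophages had 1 member lower of 20, and 9 when adjusted over the list alone (camera adjusted p = 6.9e-07, adjusted p = 0.45 with an estimated correlation). Heat shock genes had none past the test over all genes and 3 higher when adjusted over the list alone (camera adjusted p = 0.0026, adjusted p = 0.75 with an estimated correlation). Complement genes had none and 3 lower when adjusted over the list alone (camera adjusted p = 0.0035, adjusted p = 0.77 with an estimated correlation, and camera adjusted p = 0.085 without tMCAO_DE 1).

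The interaction passed in 8 genes, against 1647 at an unadjusted p under 0.05 and 114 past the adjusted threshold with DESeq2. It passed in 2 and 3 genes without sham_CON replicates 1 and 3, in 15, 5 and 1 without sham_DE replicates 1, 2 and 3, and in 3 and 5 without tMCAO_DE replicates 1 and 2. With sham_CON replicate 2 and sham_DE replicate 3 both left out, Yipf6 was the 1 gene that passed, and the other 7 were at edgeR adjusted p = 0.085 to 0.098. Yipf6 passed whichever library was left out, with an adjusted p of at most 0.0039 by edgeR's quasi-likelihood test. Calls ended for Ccl12 (up to 0.11) without sham_CON 1 or 3, sham_DE 3 or either tMCAO_DE library, and for Lilr4b (0.11) without these or sham_DE 2. They ended for Lilrb4a (0.099) without sham_CON 1, sham_DE 3 or either tMCAO_DE library, and for Cd180 (0.17) without any sham_CON library, sham_DE 2 or 3 or either tMCAO_DE library. Lpl was lost (0.18) without sham_CON 2 or 3, sham_DE 3, tMCAO_CON 2 or either tMCAO_DE library, Tlr13 (0.18) without any library except sham_DE 1 or 4, and Lingo3 (0.18) without any except sham_DE 1 or 4 or tMCAO_CON 4.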

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

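Of the tests here, the one on the homeostatic microglia list was chosen only after its result was seen.

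Gaps between the highest or lowest library and the rest of a group of 4 were large for 21 of 246 groups tested over the named genes, and for 60 of 642 over all genes the rule named. Chance gives about 1 in 20 for normally distributed values, a rate that does not hold for genes with few counts. Some flags rest on few counts, with 1 for Il6 and 3 for Cxcr2 in sham_DE and 4 for Mpo in tMCAO_CON. In sham_DE, replicate 1 was highest for Syp (1270 CPM), Msmo1 (35.8) and Cdk1 (0.973) and lowest for Mmp12 (0.0541). Replicate 2 was highest for Egr1 (837 CPM), Egr2 (46.1) and Ccl3 (0.409), and replicate 3 for Cxcr2 (0.183) and Gpr34 (1.46). Replicate 4 was highest for Il6 (0.057 CPM) and lowest for P2ry13 (0.171) and Tnf (0). In tMCAO_CON, replicate 3 was highest for Pja1 (72.5 CPM), Lgals3 (10.8), Timp1 (8.94), Tnfrsf25 (4.35) and Folr2 (1.53). Replicate 1 was highest for Mpo (0.221 CPM) and lowest for Stmn2 (251), replicate 2 highest for Gucy2c (1.25) and replicate 4 for Prelp (20.5).

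Genes listed in only the sham or only the tMCAO tables, which were tested only in an alternative with counts of 0 filled in, held counts of tissue-restricted transcripts. The intestinal genes Clca1 and Mptx1 had 232 and 101 counts in sham_DE replicate 3. The fibrinogen gene Fga had 78 of 180 counts in tMCAO_DE replicate 1, the insulin gene Ins2 75 of 150 in sham_CON replicate 2 and growth hormone, Gh, 59 in sham_CON replicate 1.

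The occlusion change differed with depletion, by the interaction in edgeR's quasi-likelihood test, in 8 genes. It was lower in depleted mice for Ccl12 (-6.65), Lilr4b (-6.41, a fitted value resting on 2 counts in sham_CON), Lilrb4a (-4.08), Cd180 (-3.06), Lpl (-2.18), Tlr13 (-1.64) and Yipf6 (-1.51), and higher for Lingo3 (0.80). Fewer microglia left after occlusion in depleted brains could give such a difference. The interaction median over the 20 homeostatic microglia genes was -0.39, against a median of -3.06 for the 7 genes. Its standard error of 0.17 is that of a mean over genes of the same libraries, so it measures no spread over animals. The level used for comparison was a share of the median of genes picked for a negative interaction. The test therefore does not decide on this explanation. Counts near 0 in sham_CON could inflate the fold for Ccl12, Lilr4b and Lilrb4a, with 4, 2 and 11 counts there. Cd180, Tlr13, Lpl and Yipf6 had 103 to 2346. With 10 counts added to each value the median of the 7 genes was -2.54 and 7 of 7 stayed below 0. The 7 were chosen for a negative interaction and most had higher counts, so this does not decide for Ccl12, Lilr4b and Lilrb4a. A difference in what the remaining or entering cells express after stroke stays open and was not tested. Yipf6 passed with any library left out, whereas each of the other 7 lost its call in at least 4 of the 13 leave-one-out fits.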

How the results depend on the processing

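Chosen after the data were seen were a robust prior, counts of 0 for genes missing from a pair of tables, the joint removal of sham_CON 2 and sham_DE 3, and the removal of genes whose counts jump within a group. The fit on log2 FPKM with a pseudocount of 1 was the planned test for FPKM values and became an alternative once counts were found. No named gene or list turned its direction past the test. The share of higher genes among calls crossed 50% in some settings. Between sham_DE and sham_CON it went from 60.4% to 37.4% without sham_CON 2 and sham_DE 3. For the interaction it went from 12.5% to 57.1% with library weights in limma and to 60% without tMCAO_DE 2. For tMCAO_DE against sham_DE it went from 53% to 48% with DESeq2, 48.4% without its filter and 49.2% with quantile normalisation. For tMCAO_DE against tMCAO_CON, near even at 50.3%, the settings that crossed gave 40% (log2 FPKM) to 49.8%, with 45.1% without tMCAO_DE 2. Of the numbers of called genes over all alternatives, 114 stayed within 1.5 times the value reported and 41 moved further. For named genes 5371 calls were the same, 282 were lost and 24 gained, and for lists 3499, 154 and 87. Of the called named genes, 35 of 45 were called in every setting for tMCAO_CON against sham_CON, 16 of 32 for tMCAO_DE against sham_DE, 24 of 40 for sham_DE against sham_CON, 15 of 39 for tMCAO_DE against tMCAO_CON and 1 of 8 for the interaction.

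Leaving out each library in turn gave 564 to 1814 genes for tMCAO_CON against sham_CON, 453 to 2096 for tMCAO_DE against sham_DE, 591 to 3725 for sham_DE against sham_CON, 346 to 3873 for tMCAO_DE against tMCAO_CON and 1 to 15 for the interaction. The lowest values came without sham_CON 3 (564 and 591), tMCAO_DE 2 (453 and 346) and sham_DE 3 (1), and the highest without sham_DE 1, except for 2096 without tMCAO_CON 3. With 1 tMCAO_DE library left, it was assumed to vary like the other groups. Without tMCAO_CON 4 the numbers were 1241, 1904, 1664, 2373 and 8 in the same order. Without sham_CON 2 and sham_DE 3 together, 219 genes remained called between sham_DE and sham_CON and 1 for the interaction. No other pair was left out for comparison.

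A filter of at least 5 FPKM, which tests fewer genes, gave 902 for tMCAO_CON against sham_CON, 1214 for sham_DE against sham_CON, 1936 for tMCAO_DE against tMCAO_CON and 2 for the interaction. Requiring a 2-fold change gave 465, 477, 555 and 730 for tMCAO_CON against sham_CON, tMCAO_DE against sham_DE, sham_DE against sham_CON and tMCAO_DE against tMCAO_CON. Fitting only the compared groups, with fewer libraries, gave 1137 for tMCAO_DE against sham_DE and 645 for sham_DE against sham_CON. Library weights in limma gave 3630 for sham_DE against sham_CON. The interaction had 114 genes with DESeq2, 111 without a filter, and 13 and 14 with limma on log2 FPKM at pseudocounts of 1 and 0.1. The cause of these shifts was not tested except where stated.

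Replicate numbers as a block gave 1341 for tMCAO_DE against sham_DE, 823 for sham_DE against sham_CON and 2 for the interaction. Deviations of same-numbered libraries correlated between -0.06 and 0.11, and 4 libraries correlated best with their own number, so the numbers were not taken as pairs.

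Among the 35 splits of the 7 libraries of tMCAO_CON and sham_CON into 4 and 3, only the real one (1 split) reached its 1430 genes, the highest other calling 125. With 35 splits, 1 is the lowest number attainable, and every other split mixes occluded and sham libraries. The test by itself therefore cannot exclude chance. Of the 35 splits of sham_DE and sham_CON, 2 reached 1921, the other calling 3526 with sham_DE 1 placed among the sham_CON libraries. That split is the real one with sham_DE 1 moved, so it still carries much of the real difference, and the test does not decide on chance. It points to a structure of the samples. The depletion comparison after occlusion shared no library with this one. In both, 605 genes were higher and 422 lower, against 108.7 and 70.4 for independent lists, with 10 opposite. Those expected numbers treat genes as independent, whereas many genes vary together across libraries. The overlap shows the same direction in separate animals but does not by itself exclude chance.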

Other observations

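The tests of library depth, genomic DNA and the loss of microglia were chosen after their results were seen, as were the conditions on single libraries and on listed genes in the test of pancreas or gut tissue. The genes named in the first paragraph on fibroblasts and the clock and glucocorticoid genes were named after their values were seen.

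Genes of fibroblasts and meninges rose after occlusion with microglia present in 4 of 10 members, 6 when adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.18 with an estimated correlation). After occlusion of depleted mice none of 10 passed (camera adjusted p = 0.81). The interaction test of the list passed (camera adjusted p = 0.0026, adjusted p = 0.75 with an estimated correlation, camera adjusted p = 0.085 without tMCAO_DE 1), with none past the test over all genes and 3 lower when adjusted over the list alone. The collagen gene Col1a1 was at 3.75 ± 0.546 CPM in sham_CON, 5.15 ± 2.13 in sham_DE, 14.8 ± 7.12 in tMCAO_CON and 4.85 ± 1.38 in tMCAO_DE. Its change with occlusion was 1.98 ± 0.38 in controls (edgeR adjusted p = 0.0069) and -0.08 ± 0.42 in depleted mice (edgeR adjusted p = 0.92), with an interaction of -2.06 ± 0.56 (edgeR adjusted p = 0.28). Decorin, Dcn, of the same list differed less between the treatments, at 2.02 ± 0.44 in controls (edgeR adjusted p = 0.014, up to 0.067 without sham_CON 1 or 3) and 1.29 ± 0.45 in depleted mice (0.079, and 0.0086 without tMCAO_CON 3), with an interaction of -0.73 ± 0.63 (0.74). Pericyte and smooth muscle genes rose in controls in 5 of 11, 6 when adjusted over the list alone (camera adjusted p = 0.016, adjusted p = 0.29 with an estimated correlation, camera adjusted p = 0.061 without sham_CON 1). In depleted mice 1 of 11 was higher with occlusion, and 2 higher and 3 lower when adjusted over the list alone (median -0.21, camera adjusted p = 0.98). After occlusion, 3 of 11 were lower in depleted than in control mice, 4 when adjusted over the list alone (camera adjusted p = 0.23). The interaction test of the pericyte list did not pass, with none past the test over all genes and 3 lower when adjusted over the list alone (camera adjusted p = 0.066, adjusted p = 0.77 with an estimated correlation). It passed without sham_DE 3 or 4, tMCAO_CON 1 or 2 or tMCAO_DE 2, with a camera adjusted p of at most 0.045. Matrix and protease genes rose with occlusion in 9 of 16 in controls, 10 when adjusted over the list alone (camera adjusted p = 4.4e-09, adjusted p = 0.09 with an estimated correlation). In depleted mice 8 of 16 rose, 9 when adjusted over the list alone (camera adjusted p = 1.3e-06, adjusted p = 0.18 with an estimated correlation). Adamts1, a secreted protease, rose by 2.17 ± 0.23 in controls (edgeR adjusted p = 0.00017) and 3.13 ± 0.24 in depleted mice (1.5e-05), and the matrix protein Tnc by 3.10 ± 0.44 (0.0015) and 2.94 ± 0.47 (0.0023).

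Ribosomal protein genes rose slightly with occlusion, in 6 of 16 in controls, 10 when adjusted over the list alone (median 0.20, camera adjusted p = 3.1e-05, adjusted p = 0.11 with an estimated correlation). In depleted mice 6 of 16 rose, 9 when adjusted over the list alone (median 0.27, camera adjusted p = 1.7e-05, adjusted p = 0.18 with an estimated correlation). Genes of the p53 pathway and apoptosis rose in 5 of 15 in controls, 6 when adjusted over the list alone (camera adjusted p = 2.6e-06, adjusted p = 0.028 with an estimated correlation). In depleted mice 6 of 15 did, 8 when adjusted over the list alone (camera adjusted p = 4.8e-05, adjusted p = 0.077 with an estimated correlation). Hypoxia and glycolysis genes fell with depletion in sham mice in 2 of 15, 5 when adjusted over the list alone (camera adjusted p = 0.0073, adjusted p = 0.63 with an estimated correlation). After occlusion 3 were higher and 1 lower with depletion, the same when adjusted over the list alone (camera adjusted p = 0.98). With occlusion in depleted mice 5 of 15 rose, 6 with 1 lower when adjusted over the list alone (camera adjusted p = 0.021, adjusted p = 0.33 with an estimated correlation). The interaction of that list passed upward with none past the test over all genes and 1 higher when adjusted over the list alone (camera adjusted p = 0.0026, adjusted p = 0.63 with an estimated correlation). The astrocyte genes named A1 in earlier work rose with occlusion in 5 of 12 in controls, 9 when adjusted over the list alone (camera adjusted p = 1.3e-06, adjusted p = 0.11 with an estimated correlation). In depleted mice 7 of 12 did, 7 when adjusted over the list alone (camera adjusted p = 5.8e-05, adjusted p = 0.27 with an estimated correlation). Chemokines of the CC family were 6 higher and 1 lower of 9 in controls, 7 and 1 when adjusted over the list alone (camera adjusted p = 3.8e-06, adjusted p = 0.11 with an estimated correlation). In depleted mice 4 of 9 were higher, 4 with 1 lower when adjusted over the list alone (camera adjusted p = 0.032, adjusted p = 0.48 with an estimated correlation, camera adjusted p = 0.11 without tMCAO_DE 2).

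Over 1960 genes below 0.05 CPM in sham_CON, which are low there by selection, summed levels were 95.2 to 281.1 CPM in depleted libraries and 127.5 to 190.9 in tMCAO_CON, the control not used to choose them. A first test of depth, thinning to equal totals, was undecided at a ratio of detected genes of 1.26 (bounds 1.2 and 1.5), and a second, chosen after it, found 5 of 6 depleted libraries above every tMCAO_CON library, which argues against depth for those 5. Pancreas or gut tissue in the sample stays open, because its test is void with only 13 of 20 listed transcripts in the tables and a comparison with genes from the top of the pattern. The listed transcripts summed to 4 CPM (median of depleted libraries; 2.35 in controls) and to 15.7 CPM in sham_DE 3, the library with the Clca1 and Mptx1 counts. Genomic DNA stays open and may be a source. The summed level of 39 chemosensory receptor genes was 2.36-fold that in tMCAO_CON, against 1.55-fold for the rest of the set, a ratio of 1.52. The test of loss of microglia was undecided, with 5 of 6 depleted libraries above every control and sham_DE 1 below those of tMCAO_CON. Csf1r in sham_DE 1 was at 7.57 CPM, within the range of the depleted libraries. Loss of microglia alone therefore did not set the level in that library.

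Clock output genes were higher in depleted libraries, in 6 of 10 evening genes in sham mice (median 0.75) and 3 of 10 after occlusion (median 0.37). Nr1d1, a repressor of the clock whose counts vary widely within groups, changed by 1.80 ± 0.31 in sham mice (edgeR adjusted p = 0.0057) and 1.48 ± 0.32 after occlusion (0.009, and 0.093 without tMCAO_DE 2). Per1 changed by 1.16 ± 0.22 (0.0087) and 0.86 ± 0.23 (0.024, up to 0.23 without tMCAO_CON 1 or 3 or either tMCAO_DE library). Another time of day at tissue collection would move Arntl, Npas2 and Clock the opposite way. Their medians were 0.04 and 0.11, near 0. The standard errors of the mean over these genes, 0.16 and 0.21, measure no spread over animals. Arntl rose by 0.47 in sham mice (edgeR adjusted p = 0.036, up to 0.11 without any sham_CON library, sham_DE 2, 3 or 4 or tMCAO_CON 3). After occlusion it rose by 0.53 (edgeR adjusted p = 0.023), a call that ended without tMCAO_CON 2 or 3 or tMCAO_DE 2. Time of day and depletion cannot be told apart. For a glucocorticoid response in depleted mice, the median of 9 targets was 0.60 in sham mice and 0.65 after occlusion, with 1 of 9 and 4 of 9 past the test. Among those not past it, Tsc22d3 changed by 0.04 (edgeR adjusted p = 0.86) and 0.16 (0.43). Sgk1, the target past the test in sham mice, rose by 0.61 (edgeR adjusted p = 0.04). Its call ended without any sham_CON library or sham_DE 2, 3 or 4. A glucocorticoid response stays open.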
